A study of Mus musculus with 12 samples.

How the data were processed

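The assay was SLAM-seq, which marks RNA made during a pulse of 4-thiouridine. Per the labels' protocols, SIM-A9 cells received 10 µM polymyxin B for 1 h, 10 µM C13 or DMSO for 1 h, and 5 µg/mL of TDP-43 or sham aggregates for 2.5 h, after which 100 µM 4-thiouridine was present for 90 min, giving 4 h with aggregates. RNA was treated with iodoacetamide, so that labelled bases are read as changed, and libraries of mRNA 3′ ends were made. Since such reads mark 3′ ends, no correction for gene length was made. The authors deposited raw counts per Ensembl gene in 2 tables, nascent and total, each with 30994 genes and 12 libraries. The build was GRCm38, per the submitters' processing notes. The aligner, the counter, the annotation and the number of base changes that makes a read nascent are not given in the sources used here. No nascent count exceeded the total count of the same gene and library.

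Symbols and positions were taken from a GRCm38 annotation, which matched 30922 of the gene identifiers. Groups and replicate numbers came from the labels, which call the samples biological replicates and state no shared day. No 2 replicates of a group were the same library, since chi-square per degree of freedom between replicates was 67.6 or more. Genes were kept by filterByExpr, leaving 7078 nascent and 11827 total genes. Counts were scaled by TMM within each table and compared with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test, with all 12 libraries in 1 fit of 4 group means. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Scaling within the nascent table removes a global change in labelled RNA, so the nascent share of each library was compared separately by exact permutation within the other treatment's arms, over 400 arrangements. CPM values use the TMM-scaled library sizes.

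Before the data were examined, 30 gene lists, the comparisons and the rule for naming genes were fixed. Of the lists, 24 had at least 5 tested members. They were tested by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and by fry. The rule named up to 10 rising and 10 falling genes per pairwise nascent comparison among those past the threshold with a mean of at least 20 reads in the higher group and replicates that did not overlap. It also named 5 genes of the interaction, up to 4 members of each list with the smallest p in the comparison, and the genes Mok, Tardbp, Il6, Tnf, Il1b, Ifnb1, Cxcl10, Nos2, Myc and Hmox1. Another gene fixed in advance is not reported here. No gene met its first part or passed the interaction test. To ask whether nascent reads of a gene moved apart from its other reads, both kinds of count were put in 1 edgeR fit with the library as a term.

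The alternatives were DESeq2's size factors, no filter, DESeq2 1.42.0, a replicate block, leaving out each library, only the groups compared, and the library sizes of the total table for nascent counts. Leaving out 2 libraries that stood apart, dividing counts by a common factor, and voom with sample weights were added after seeing the data, as were the lists without each library in turn and an exact permutation test of nascent CPM of the fixed genes Mok, Myc and Nos2, which the filter removed. In 1917 of 9932 genes with a mean of over 50 total reads, all 24 counts shared a factor of 2 or more, for which the sources used here give no reason.

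The tests were checked on counts simulated from the real means, spread and library sizes, in 3 runs per case. With nothing changed, edgeR made 0 calls on average for C13 against DMSO with aggregates in nascent RNA, among 7113 genes, and DESeq2 made 2. With 200 genes changed in that comparison, among 7239 genes, edgeR recovered 0% of genes changed 2-fold, 2.67% at 4-fold, 14.7% at 8-fold and 38% at 16-fold, with 0.333 false calls on average, and DESeq2 made 34.3 false calls among 82.3. In total RNA, among 11832 genes, edgeR recovered 16.7%, 52.7%, 69.3% and 80.7%. When the interferon list was doubled in the averaged aggregate comparison, camera called it in 3 of 3 runs in each table and called 0 other lists. With an estimated correlation it was called in 2 of 3 runs in nascent and 3 of 3 in total RNA. Genes were simulated independently of each other, so these runs do not show how often camera wrongly calls a list whose members are correlated. Without the filter, edgeR's prior degrees of freedom were infinite, so that all genes shared 1 spread, against 9.84 in nascent and 7.11 in total RNA with it.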

Results

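RNA made during a short pulse and total RNA were counted in SIM-A9 cells, a mouse microglial line from the C57BL/6 strain. Microglia are the resident macrophages of the brain. Cells received C13, a compound that the series title calls an inhibitor of the kinase MOK, or its solvent DMSO, and then aggregates of the RNA-binding protein TDP-43 or a sham preparation. All cells were first given polymyxin B, an antibiotic that binds bacterial endotoxin. The 4 groups were DMSO with sham, DMSO with TDP-43, C13 with sham and C13 with TDP-43, with 3 libraries each. The libraries held 17436397 to 41779882 total reads, of which 552042 to 2722812 were nascent.

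The first question was whether C13 or the aggregates changed the amount of newly made RNA as a whole. The nascent share of a library ran from 1.88% (95% Clopper-Pearson interval 1.88% to 1.89%) in C13 with sham replicate 3 to 7.11% (95% Clopper-Pearson interval 7.10% to 7.11%) in DMSO with sham replicate 2. These intervals cover counting error only and take every counted read as independent. Since counts of 1917 genes shared a factor of 2 or more, they may be too narrow even for counting error. The mean share was 4.42% ± 2.35 (SD, n = 3) in DMSO with sham, 2.77% ± 0.610 (SD, n = 3) in DMSO with TDP-43, 2.64% ± 0.683 (SD, n = 3) in C13 with sham and 2.91% ± 0.435 (SD, n = 3) in C13 with TDP-43. Libraries with C13 differed from those with DMSO by -0.816 percentage points (two-sided exact permutation test within the aggregate arms, p = 0.385). Libraries with aggregates differed from sham libraries by -0.694 percentage points (two-sided exact permutation test within the drug arms, p = 0.52). Without DMSO with sham replicate 2 these differences were -0.144 and -0.0218 percentage points (exact permutation p = 0.715 and 0.95), and without DMSO with sham replicate 3 they were -1.23 and -1.11 (exact permutation p = 0.18 and 0.245).

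**Figure D1:**
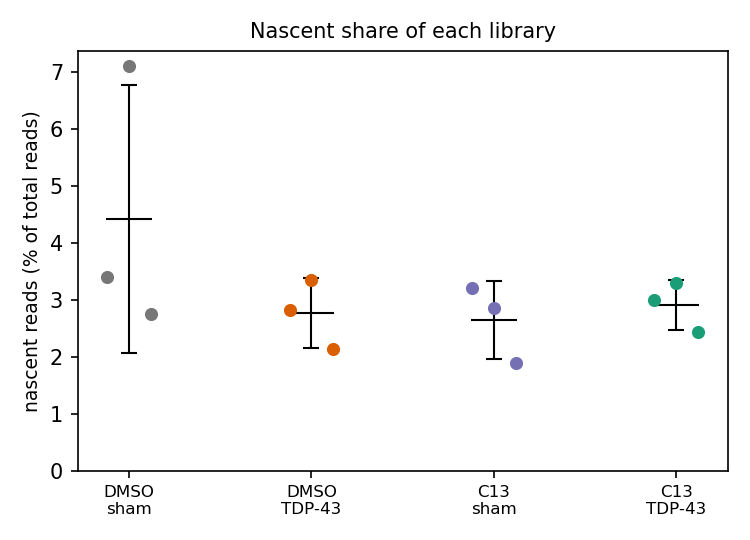
Nascent reads as a percent of total reads (vertical axis) in each of the 12 libraries, by group. Points are libraries, and bars are the group mean with its SD (n = 3); one library of DMSO with sham stands at 7.11%, and the lowest library is at 1.88%.

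Aggregates were next compared with sham in cells given DMSO, to describe the response to TDP-43 without the inhibitor. Cxcl2, Ccl4 and Ccl5, of the list of inflammatory mediators, had higher values with aggregates, and 0 genes of the list were called in either table (adjusted over the list alone). Nascent Cxcl2, a chemokine that attracts neutrophils, had 343 ± 136 CPM with sham and 984 ± 240.1 CPM with aggregates (SD, n = 3), a log2 fold change of 1.52 (SE 0.49). Nascent Ccl4, a macrophage chemokine, had 184 ± 89.6 and 561 ± 120.2 CPM (SD, n = 3). In total RNA, Ccl5, a chemokine that attracts T cells, had 2.41 ± 0.759 and 7.46 ± 0.296 CPM, and Ccl4 had 20.2 ± 1.34 and 38.4 ± 2.89 CPM (SD, n = 3). The list of inflammatory cytokines, chemokines and enzymes rose in nascent RNA, with 9 of 11 tested members higher (camera adjusted p = 5.73e-04), and this call was lost with adjusted p = 0.226 with an estimated correlation. It also rose in total RNA, with 14 of 21 members higher (camera adjusted p = 0.0298), and adjusted p = 0.184 with an estimated correlation.

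Values of other mediators went both ways. Nascent Tnf, the gene of tumour necrosis factor, had 1123 ± 697 CPM with sham and 1599 ± 655 CPM with aggregates (SD, n = 3), while total Tnf had 65.9 ± 9.09 and 63.4 ± 8.68 CPM (SD, n = 3). Nascent Il1b, the gene of interleukin 1 beta, had a log2 fold change of -1.22 (SE 1.42). Scaled by the library sizes of the total table, the median log2 fold change of all nascent genes was -0.84 in place of -0.04, that of Tnf was -0.082 and that of the cytokine list was -0.27, and the list's call was lost (camera adjusted p = 0.167, with an upward direction against other genes). Nascent Rsad2, an antiviral enzyme induced by interferon, had a log2 fold change of 1.51 (SE 0.55), and the type I interferon list was just short of the threshold, with 13 of 15 members higher in nascent RNA (camera adjusted p = 0.0602) and 22 of 33 in total RNA (camera adjusted p = 0.0623). Total Hspa4, a heat shock protein of the HSP110 family, had 295 ± 125 and 138 ± 36.4 CPM (SD, n = 3) and was the 1 heat shock gene called (adjusted over the list alone, edgeR adjusted p = 0.0436). Over all genes, edgeR called 0 of 7078 in nascent and 0 of 11827 in total RNA. An unadjusted p under 0.05 was found for 226 and 516 genes, against 353.9 and 591.35 by chance, and DESeq2 called 7 and 8 genes. Mitochondrial ribosomal RNA took 1.32% ± 0.160 of total reads in DMSO with sham and 2.23% ± 0.453 in DMSO with TDP-43 (SD, n = 3), with 2.47% in DMSO with TDP-43 replicate 3. That library stood apart from the rest on the first principal component and by its number of genes at a common depth, 11166. The nascent cytokine call was lost without DMSO with sham replicate 2 (camera adjusted p = 0.478). The median log2 fold change of that list went from 0.51 to 0.078 without that library and to 0.235 without DMSO with TDP-43 replicate 3. The call in total RNA was lost without DMSO with sham replicate 1 or 2 or DMSO with TDP-43 replicate 2 (camera adjusted p = 0.0863, 0.11 and 0.236).

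In cells given C13, aggregates were again compared with sham, and interferon-induced genes are given first. Total Cxcl10, a chemokine induced by interferon, had 10.2 ± 3.66 CPM with sham and 45.2 ± 23.2 CPM with aggregates (SD, n = 3), a log2 fold change of 2.15 (SE 0.41). Total Isg15, a ubiquitin-like modifier, had 18.8 ± 11.1 and 59.2 ± 17.5 CPM, and total Rsad2 had 51.7 ± 9.75 and 120.3 ± 25.2 CPM (SD, n = 3). With Rtp4, at 2.94 ± 0.992 and 10.97 ± 3.303 CPM, these were the 4 interferon genes called in total RNA (adjusted over the list alone, edgeR adjusted p = 0.00303 to 0.0161), and none of them passed over all genes. The type I interferon list rose in total RNA, with 31 of 33 members higher and a median log2 fold change of 0.82 (camera adjusted p = 7.01e-08), with adjusted p = 0.0571 with an estimated correlation. Without C13 with sham replicate 2 that median was 1.29. In nascent RNA it rose with 11 of 15 members higher (camera adjusted p = 0.0358), with adjusted p = 0.227 with an estimated correlation, and 3 of its genes were called (adjusted over the list alone). Nascent Isg15 had 71.7 ± 72.8 and 406 ± 99.9 CPM (SD, n = 3), while nascent Irf7, a regulator of the interferon response, had 0 reads in every C13 with sham library.

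Further groups moved in total RNA under C13. The cytokine list rose, with 16 of 21 members higher (camera adjusted p = 0.0099, and adjusted p = 0.0764 with an estimated correlation). Total Tnf had 49.5 ± 16.97 CPM with sham and 87.2 ± 14.1 CPM with aggregates (SD, n = 3). Ccl4 had 23.6 ± 9.28 and 27.6 ± 11.8 CPM in total RNA and 317 ± 274 and 283 ± 181 CPM in nascent RNA (SD, n = 3). Of the list of NF-kB subunits and feedback genes, 2 were called (adjusted over the list alone), Bcl2a1b and Traf1, with log2 fold changes of 1.33 (SE 0.27) and 0.74 (SE 0.19), while the list itself did not pass (camera adjusted p = 0.134). Bcl2a1b, an anti-apoptotic gene, has near-identical copies and overlaps another gene on its strand, so its count is uncertain. Cytosolic ribosomal protein genes fell, with 29 of 39 lower (camera adjusted p = 0.021), and adjusted p = 0.805 with an estimated correlation.

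Over all genes, edgeR called 0 in nascent and 0 in total RNA for aggregates against sham under C13, with 598 and 1045 genes at an unadjusted p under 0.05, and DESeq2 called 72 and 98. Without C13 with sham replicate 1, edgeR called 1 and 4 genes. Mitochondrial ribosomal RNA took 2.62% ± 0.972 of total reads in C13 with sham and 1.45% ± 0.139 in C13 with TDP-43 (SD, n = 3), with 3.70% in C13 with sham replicate 3. That library stood apart from the rest on the first principal component, as did DMSO with TDP-43 replicate 3. Without these 2 libraries the cytokine and nascent interferon calls were lost (camera adjusted p = 0.0727 and 0.0915), while the median log2 fold changes of the lists were 0.44 in place of 0.39 and 1.38 in place of 1.30, and edgeR called 1 gene in total RNA. The nascent interferon call was lost without C13 with sham replicate 1, 2 or 3 or C13 with TDP-43 replicate 2 or 3 (camera adjusted p = 0.238, 0.0561, 0.184, 0.0916 and 0.161), with a median of 2.20 without the first of these and 2.17 without the second. The cytokine call was lost without C13 with sham replicate 3 or C13 with TDP-43 replicate 2 (camera adjusted p = 0.0623 and 0.0529), and the ribosomal call without C13 with sham replicate 1 or 2 or C13 with TDP-43 replicate 3 (camera adjusted p = 0.114, 0.964 and 0.903).

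**Figure D2:**
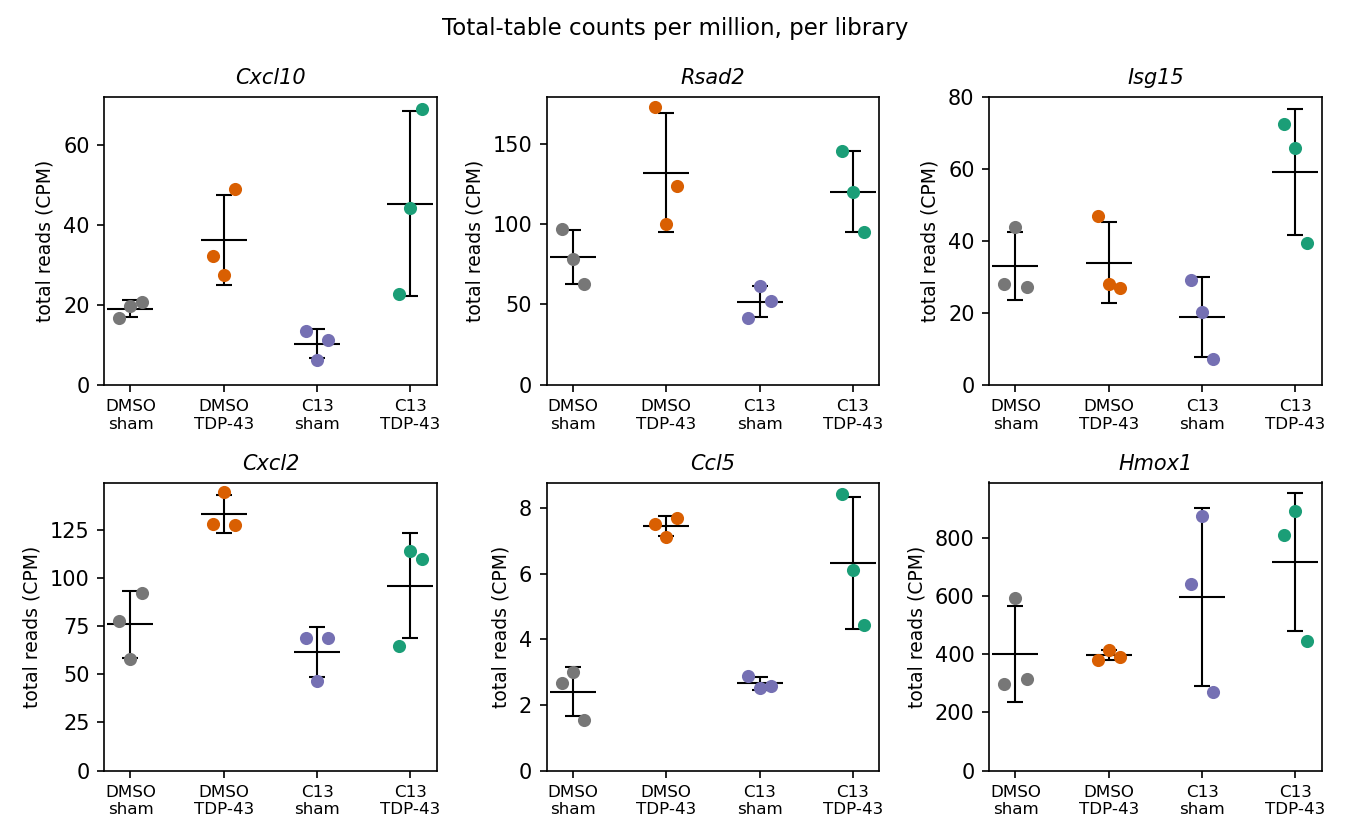
CPM of 6 genes in the total table (vertical axes, linear from 0) in each of the 12 libraries, by group. Points are libraries, and bars are the group mean with its SD (n = 3); Cxcl10 averages 10.2 CPM in C13 with sham and 45.2 CPM in C13 with TDP-43.

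Averaged over both drug arms, aggregates went with higher interferon and cytokine genes in both tables. Total Cxcl10 had a log2 fold change of 1.54 (SE 0.28) and total Rsad2 one of 0.98 (SE 0.18), and nascent Rsad2 had one of 1.33 (SE 0.39). The interferon list rose in nascent RNA, with 12 of 15 members higher (camera adjusted p = 1.11e-04, and 0.0353 with an estimated correlation), and in total RNA, with 29 of 33 higher (camera adjusted p = 1.12e-09, and 0.014 with an estimated correlation). The cytokine list rose in nascent RNA, with 11 of 11 higher (camera adjusted p = 4.5e-05, and adjusted p = 0.203 with an estimated correlation), and in total RNA, with 18 of 21 higher (camera adjusted p = 1.59e-05, and 0.014 with an estimated correlation). Interferon genes called numbered 5 in nascent and 3 in total RNA, and cytokine genes 1 and 2 (adjusted over the list alone). The cytokine genes were Cxcl2 in both tables, with log2 fold changes of 1.28 (SE 0.35) and 0.73 (SE 0.18), and Ccl5 in total RNA, with 1.44 (SE 0.38).

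Other lists moved less firmly in that average. Ribosomal protein genes fell in total RNA, with 36 of 39 lower (camera adjusted p = 1.56e-04), and adjusted p = 0.852 with an estimated correlation. Antigen presentation genes rose, with 15 of 20 higher (camera adjusted p = 0.0378), and adjusted p = 0.387 with an estimated correlation. The ribosomal call was lost without DMSO with sham replicate 2, C13 with sham replicate 2 or C13 with TDP-43 replicate 3 (camera adjusted p = 0.393, 0.187 and 0.184). That of antigen presentation was lost without DMSO with sham replicate 1 or 3, DMSO with TDP-43 replicate 2, C13 with sham replicate 3 or C13 with TDP-43 replicate 1 or 2 (camera adjusted p = 0.127, 0.158, 0.173, 0.214, 0.0619 and 0.0867). The averaged comparison in total RNA was added after seeing the data. Over all genes in total RNA edgeR called 0, with 560 at an unadjusted p under 0.05, and DESeq2 called 33.

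In nascent RNA 1 gene passed over all genes in the averaged comparison, and DESeq2 called 9. This was Mff, which encodes a receptor for mitochondrial fission and was chosen after its values were seen. Nascent Mff fell by 4.35 on the log2 scale (SE 0.67, edgeR adjusted p = 0.0286). It had 259 ± 87.9 CPM in DMSO with sham, 9.82 ± 1.87 in DMSO with TDP-43, 104 ± 84.8 in C13 with sham and 6.48 ± 1.40 in C13 with TDP-43 (SD, n = 3). Total Mff had a log2 fold change of -0.02 (SE 0.15). Mff overlaps 2 other annotated genes, 1 of them on its strand. The call was lost without any 1 of 10 of the 12 libraries (edgeR adjusted p up to 0.298), the exceptions being C13 with sham replicates 2 and 3.

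The comparison named by the series title was C13 against DMSO in cells given aggregates. No gene list passed in either table. Nascent Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, had 1013 ± 239 CPM with DMSO and 2189.5 ± 821 CPM with C13 (SD, n = 3), a log2 fold change of 1.11 (SE 0.48, edgeR adjusted p = 0.998). Total Hmox1 had 396 ± 16.8 and 716 ± 238 CPM (SD, n = 3). Of inflammatory genes, nascent Tnf had a log2 fold change of 0.32 (SE 0.52) and nascent Il1b one of 1.83 (SE 1.45). The interferon list had 5 of 15 members higher in nascent RNA, with a median log2 fold change of -0.49, while camera's direction was upward (adjusted p = 0.939). Nascent Cyld, a deubiquitinase that restrains NF-kB, had a log2 fold change of 2.45 (SE 0.71, edgeR adjusted p = 0.99).

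For that comparison edgeR called 0 genes in nascent and 0 in total RNA, with 325 and 707 at an unadjusted p under 0.05, and DESeq2 called 11 and 30. Whether nascent reads of a gene moved apart from its other reads was tested in edgeR over 7078 genes. It called 0 for C13 against DMSO with aggregates and 0 for aggregates against sham with DMSO, with 251 and 188 at an unadjusted p under 0.05; DESeq2 was not run on this test.

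Without aggregates, the interferon list was lower with C13 than with DMSO in total RNA. Total Cxcl10 had 19.0 ± 2.09 CPM with DMSO and 10.2 ± 3.66 CPM with C13, and total Rsad2 had 79.5 ± 16.9 and 51.7 ± 9.75 CPM (SD, n = 3). The interferon list fell in total RNA, with 23 of 33 members lower and a median log2 fold change of -0.54 (camera adjusted p = 0.0436), and adjusted p = 0.808 with an estimated correlation. In nascent RNA it did not pass, with 9 of 15 members lower (camera adjusted p = 0.904). Of its members, 0 were called in total RNA (adjusted over the list alone). Total Hspa4 had a log2 fold change of -1.32 (SE 0.31) and was called over the heat shock list (adjusted over the list alone, edgeR adjusted p = 0.00986). Nascent Hmox1 had 817 ± 309 CPM with DMSO and 1720 ± 988 CPM with C13, and total Hmox1 had 401 ± 165 and 596 ± 305 CPM (SD, n = 3). Scaled by the library sizes of the total table, the median log2 fold change of all nascent genes was -1.02 in place of -0.04. The size of nascent differences in this comparison thus depends on the scaling. Over all genes edgeR called 0 in nascent and 0 in total RNA, with 488 and 722 at an unadjusted p under 0.05, and DESeq2 called 29 and 41. Mitochondrial ribosomal RNA took 1.32% ± 0.160 of total reads in DMSO with sham and 2.62% ± 0.972 in C13 with sham (SD, n = 3). The interferon call was lost without DMSO with sham replicate 1 or 2 or C13 with sham replicate 1 or 3 (camera adjusted p = 0.101, 0.0995, 0.0875 and 0.473), and without the 2 libraries that stood apart (0.548, with a median of -0.43). Without C13 with sham replicate 1 the median was -0.93 and edgeR called 2 genes in total RNA.

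Averaged over both aggregate arms, C13 was compared with DMSO, and the values of 2 targets of the antioxidant regulator NRF2 are given first. Nascent Hmox1 had a log2 fold change of 1.09 (SE 0.34) and nascent Srxn1, which encodes sulfiredoxin, one of 0.94 (SE 0.32), both with an edgeR adjusted p of 0.801. Nascent Srxn1 had 307 ± 58.1 and 322 ± 69.0 CPM in the DMSO groups and 588 ± 73.1 and 617 ± 136 CPM in the C13 groups, sham first (SD, n = 3). Scaled by the library sizes of the total table, the median log2 fold change of all nascent genes was -0.45 in place of -0.02, so these nascent values depend on the scaling. The list of NRF2 targets did not pass in nascent RNA (camera adjusted p = 0.485). Over all genes edgeR called 0 in nascent RNA, with 422 at an unadjusted p under 0.05, and DESeq2 called 10.

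Whether the response to C13 differed with the aggregates was tested as an interaction. The interferon list had a positive interaction in total RNA, with 23 of 33 members higher and a median of 0.59 on the log2 scale (camera adjusted p = 0.0391), and adjusted p = 0.58 with an estimated correlation. In nascent RNA it did not pass (camera adjusted p = 0.91). Mitochondrial ribosomal RNA took 1.32% ± 0.160 of total reads in DMSO with sham, 2.23% ± 0.453 in DMSO with TDP-43, 2.62% ± 0.972 in C13 with sham and 1.45% ± 0.139 in C13 with TDP-43 (SD, n = 3). Total Hspa4 had an interaction of 2.13 on the log2 scale (SE 0.43, edgeR adjusted p = 0.132) and was called over the heat shock list (adjusted over the list alone, edgeR adjusted p = 0.00284). This call and the Hspa4 calls for aggregates with DMSO and for C13 with sham share the DMSO with sham libraries. They are not independent of each other. Over all genes edgeR called 0 in nascent and 0 in total RNA, with 537 and 941 at an unadjusted p under 0.05, and DESeq2 called 48 and 108. Across 7078 nascent genes, which are not independent replicates, the log2 fold changes of C13 with and without aggregates had a Pearson r of -0.0528 and a Spearman rho of -0.0539. The interaction, the lower interferon genes with C13 alone and the response to aggregates under C13 share the C13 with sham libraries. The list's call was lost without DMSO with sham replicate 1, DMSO with TDP-43 replicate 3, C13 with sham replicate 3 or C13 with TDP-43 replicate 2 or 3 (camera adjusted p = 0.0539, 0.0933, 0.327, 0.107 and 0.0559), or without the 2 libraries that stood apart (0.557, with a median of 0.56). The median was 0.88 without DMSO with TDP-43 replicate 1 and 0.89 without C13 with TDP-43 replicate 1. EdgeR called 3 genes in total RNA without DMSO with sham replicate 2, 1 in total RNA without C13 with sham replicate 3 and 1 in nascent RNA without C13 with sham replicate 1.

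Several genes fixed in advance had too few nascent reads to compare. Ifnb1, the gene of interferon beta, had 0 reads in all 12 libraries of both tables. Il6, the gene of interleukin 6, had 0 nascent reads and 0 to 22 total reads per library. Mok, which encodes the kinase itself, had 2 nascent reads over all libraries and 0 to 294 total reads per library. Myc, a growth regulator, had 8 nascent reads over all libraries. A change in nascent RNA of these genes was not detectable at this depth. Nos2, which encodes an enzyme that makes nitric oxide, had 48 nascent reads, too few for the filter of the gene-wise tests. They numbered 2, 20 and 1 in DMSO with sham, 9, 15 and 0 in DMSO with TDP-43, 0 in each C13 with sham library and 0, 1 and 0 in C13 with TDP-43. Nascent Nos2 differed by -5.57 CPM between C13 and DMSO libraries (two-sided exact permutation test within the aggregate arms, p = 0.02, and adjusted p = 0.12 over 6 tests of 3 genes with few reads). This test was chosen after the counts were seen, and its adjusted p ran from 0.03 without DMSO with TDP-43 replicate 3 to 0.48 without C13 with TDP-43 replicate 1 or 3. Total Nos2 had a log2 fold change of -0.57 (SE 0.66, edgeR adjusted p = 0.999) for averaged C13. Nascent Tardbp, which encodes TDP-43, had a log2 fold change of 0.25 (SE 0.56) for aggregates with DMSO and 1.44 (SE 0.57, edgeR adjusted p = 0.565) for aggregates with C13.

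The genes named most often are protein-coding, with positions in GRCm38. Cxcl10 (ENSMUSG00000034855) lies on chromosome 5 from 92346638 to 92348889 and overlaps Art3 on the other strand. Rsad2 (ENSMUSG00000020641) lies on chromosome 12 from 26442746 to 26456452, and Isg15 (ENSMUSG00000035692) on chromosome 4 from 156199424 to 156200818. Cxcl2 (ENSMUSG00000058427) lies on chromosome 5 from 90903871 to 90905938, and Tnf (ENSMUSG00000024401) on chromosome 17 from 35199381 to 35202007. Hmox1 (ENSMUSG00000005413) lies on chromosome 8 from 75093621 to 75100589, and Mff (ENSMUSG00000026150) on chromosome 1 from 82724890 to 82752394. Il1b, Tardbp, Irf7 and Cyld also overlap other genes on the opposite strand, and Rtp4 overlaps a gene on its own strand. Whether the counts used the strand is not given in the sources used here, so reads of overlapping genes cannot be told apart.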

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

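The tests in this part were chosen after seeing the data, except the list tests of the interaction and of nascent RNA, with their estimated correlation, fry and library sizes of the total table, which were planned; the last was set against an explanation after its result was seen. For cells of another type, fewer reads and a common factor, the value to be tested was set before it was computed. The difference that drew attention was between the 2 aggregate arms: the effect of C13 on the interferon list differed with and without aggregates in total RNA, by a test of the interaction itself (camera adjusted p = 0.0391). This call was lost with adjusted p = 0.58 with an estimated correlation, 0.117 by fry and 0.259 with voom weights. In 100 splits of the 12 libraries, aggregate labels were exchanged within each drug arm, and 25 gave a difference as large (0.83 for the real split and 1.47 for the highest other). Such splits can turn a rise with aggregates in both arms into an apparent interaction. They therefore do not decide whether the interaction arose by chance, and chance cannot be excluded. List values of splits are the mean log2 difference of members less that of all tested genes.

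Interferon and cytokine genes rose with aggregates when both drug arms were averaged, but the nascent cytokine call was lost, with adjusted p = 0.203 with an estimated correlation and 0.158 by fry. The 2 libraries that stood apart are argued against as the cause, since without them the adjusted p in total RNA was 9.03e-08 for interferon genes and 4.94e-04 for cytokine genes. Scaling of the nascent table is argued against for the direction of both medians. With the library sizes of the total table, the median log2 fold change was 0.98 for interferon and 0.31 for cytokine genes. That of all nascent genes was then -0.25. The camera adjusted p was 1.95e-04 for both lists, but camera compares members with other genes. A shift that all genes share is therefore largely left out of it. Endotoxin in the aggregate preparation cannot be told apart from the aggregates themselves, because 0 libraries lacked polymyxin B. A response to TDP-43, the difference that the design names, was not tested apart from the preparation and stays open.

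Splits of lists were run only for lists that camera had called in the same libraries. Their shares count the real split and are not adjusted for the lists tested, so they do not exclude chance. For the averaged rise of interferon genes in nascent RNA, 1 of 100 splits gave a value as large (0.99 for the real split and 0.96 for the highest other). In total RNA 2 of 100 did (0.74 and 0.83). For cytokine genes it was 3 of 100 in total RNA (0.36 and 0.42) and 5 of 100 in nascent RNA (0.72 and 0.94). For the lower ribosomal protein genes, with 34 of 100 splits (-0.23 and 0.52), and the higher antigen presentation genes, with 7 of 100 (0.21 and 0.29), chance cannot be excluded. For the count of nascent genes in the averaged aggregate comparison, 3 of 100 splits gave as many (1 for the real split and 1 for the highest other). Chance is not excluded for that count. That count is 1 gene, which other splits reach too, and it was lost without any 1 of 10 of the 12 libraries and with voom weights. For the nascent counts of the interaction and of averaged C13, 100 of 100 splits gave as many (0 for the real split and 1 for the highest other). For the total count of the interaction it was 100 of 100 (0 and 10). The interaction splits exchanged aggregate labels within drug arms, so an aggregate effect in both arms can appear in them as an interaction. Whether this or a structure of the samples gave the split with 10 calls was not tested. Every split reaches a count of 0, so the splits decide nothing about these 3 counts.

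With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For nascent and total counts of genes in each pairwise comparison, and for nascent against other reads in both comparisons tested, 10 of 10 splits gave as many, with 0 for the real split and 0 for the highest other, or 1 for aggregates with C13 in each table, so these splits decide nothing. For interferon genes the real split was the 1 of 10 with the largest value for aggregates with C13 in nascent (1.33 and 0.87 for the highest other) and total RNA (1.16 and 0.72) and for C13 with sham in total RNA (-0.59 and 0.55). For cytokine genes it was the 1 of 10 for aggregates with DMSO in nascent (0.79 and 0.57) and total RNA (0.45 and 0.36), and 3 of 10 were as large for aggregates with C13 in total RNA (0.28 and 0.39). For ribosomal protein genes under C13, 4 of 10 were as large (-0.37 and 0.72).

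DMSO with TDP-43 replicate 3 and C13 with sham replicate 3 stood apart from the other libraries on the first principal component. Cells of another type are argued against, since 0 of the 2 had more marker reads of other cell types than each other library (202 and 205 CPM over 48 markers, against 179 to 239 CPM). A low complexity of the library may be a cause, since 2 of 2 had fewer genes at a common depth than each other library (11166 and 11276, against 11718 to 12930). On the second principal component the 2 lay at opposite ends, at 106.7 and -105.1 in nascent and -95.2 and 88.7 in total RNA. They thus also differed from each other, and a cause common to both was not shown. No biological explanation was tested, since the 2 belong to different groups.

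Nascent counts varied more between replicates than total counts, with a biological coefficient of variation of 0.962 over the genes tested in nascent RNA and 0.602 over those tested in total RNA. Total counts thinned to the nascent depth had 0.26 over the same genes, a ratio of 0.27. This coefficient leaves out counting noise, so thinning could not raise it and the outcome was fixed in advance. Thinning also drew counts singly, so it does not show what a lower depth does to counts that are multiples. Whether fewer reads account for the higher coefficient is therefore not decided by this test. A factor shared by all 24 counts of a gene is argued against, since dividing by it left 0.939, a ratio of 0.976. Multiples in only some counts of a gene were not divided and stay open. Cxcl2 is an example, since its nascent counts were all even but its total count in DMSO with sham replicate 1 was 2463. Fewer labelled molecules stay open, and no biological explanation was tested.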

How the results depend on the processing

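Leaving out the 2 libraries that stand apart, dividing by a common factor, voom with sample weights, the test of nascent Nos2, the lists without each library in turn and the averaged list tests in total RNA were chosen after seeing the data; the other alternatives were planned. Depth limits how many genes can be tested, 7078 in nascent and 11827 in total RNA. With the real spread and 3 libraries per group, edgeR recovered 38% of genes changed 16-fold for C13 with aggregates in simulated nascent counts of 7239 genes. Both differences in nascent share kept their side of the threshold under each alternative run. The averaged interferon calls in both tables and the averaged cytokine call in total RNA were kept under each alternative run. Where no cause is given below, the cause was not tested.

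Counts of called genes moved most with the tool and the filter. In nascent RNA DESeq2 called 11 genes for C13 with aggregates, 29 for C13 with sham, 7 for aggregates with DMSO, 72 for aggregates with C13, 48 for the interaction, 10 for averaged C13 and 9 for averaged aggregates. Without a filter edgeR called 10, 29, 6, 30, 38, 11 and 18 in that order. In total RNA DESeq2 called 30, 41, 8, 98 and 108 over the first 5 of these, and edgeR without a filter 33, 59, 10, 124 and 124. Other settings moved 0 calls to 1 for aggregates with C13 in total RNA, with only the 2 groups compared and without the 2 libraries that stand apart, and to 2 with a common factor divided out and 4 with voom weights for the interaction in total RNA. The 1 nascent call of averaged aggregates became 0 with voom weights.

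Deviations of same-numbered libraries correlated at -0.0322 to 0.0585 in nascent and -0.0292 to 0.126 in total RNA. Of 12 libraries, 4 in nascent and 6 in total RNA correlated best with their own number. Replicate 3 nevertheless had the lowest nascent share in each group (2.74%, 2.13%, 1.88% and 2.44%). It also had the fewest genes at a common depth in each group (11993, 11166, 11276 and 11859). Whether the replicate numbers mark a shared batch therefore stays open. With a replicate block, averaged aggregates had 0 nascent calls, the interaction had 2 calls in total RNA, and the interferon list had adjusted p = 0.0851 for C13 with sham and 0.0704 for the interaction. The block changed no other call of a list and moved no other count by over 1.5 times.

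With an estimated correlation, the cytokine list had adjusted p = 0.226 for aggregates with DMSO and 0.203 for averaged aggregates in nascent RNA, and in total RNA 0.184 with DMSO and 0.0764 with C13. The interferon list had 0.227 in nascent and 0.0571 in total RNA for aggregates with C13, 0.808 for C13 with sham and 0.58 for the interaction. Ribosomal genes had 0.805 with C13 and 0.852 averaged, and antigen presentation genes 0.387. By fry, the cytokine list had 0.286 with DMSO and 0.158 averaged in nascent RNA and 0.489 with DMSO in total RNA, the interferon list 0.341 for C13 with sham and 0.117 for the interaction, ribosomal genes 0.779 with C13 and 0.726 averaged, and antigen presentation genes 0.255.

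Without the 2 libraries that stand apart, the interferon list had adjusted p = 0.0915 for aggregates with C13 in nascent RNA, 0.548 for C13 with sham and 0.557 for the interaction, the cytokine list 0.0727 for aggregates with C13 in total RNA, and antigen presentation genes 0.147. In that order the median log2 fold changes were 1.38, -0.43, 0.56, 0.44 and 0.21, in place of 1.30, -0.54, 0.59, 0.39 and 0.14. That of antigen presentation genes was 0.30 without DMSO with sham replicate 2, 0.24 without C13 with TDP-43 replicate 1 and 0.21 without C13 with sham replicate 1. With voom weights the interferon list had 0.051 for aggregates with C13 in nascent RNA, 0.152 for C13 with sham and 0.259 for the interaction, and antigen presentation genes 0.054. With the library sizes of the total table, the nascent cytokine list had 0.167 for aggregates with DMSO, and nascent Tnf a log2 fold change of -0.082, where the median of all nascent genes was -0.84 in place of -0.04. That median was -1.02 in place of -0.04 for C13 with sham, and 0.35 in place of 0.04 for aggregates with C13. For the interaction it was 1.19 in place of 0.09, and the median of the nascent interferon list was 1.95 in place of 0.75.

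Without each library in turn, counts ranged from 0 to 1 for nascent aggregates with C13, the nascent interaction and nascent averaged aggregates, from 0 to 2 for C13 with sham in total RNA, from 0 to 4 for aggregates with C13 in total RNA and from 0 to 3 for the interaction in total RNA. The adjusted p of the cytokine list ranged from 7.44e-04 to 0.478 for nascent aggregates with DMSO, from 0.00894 to 0.236 in total RNA with DMSO and from 0.00519 to 0.0623 with C13. That of the interferon list ranged from 0.0168 to 0.238 for nascent aggregates with C13, from 0.0319 to 0.473 for C13 with sham and from 0.00706 to 0.327 for the interaction. Ribosomal genes ranged from 1.7e-08 to 0.964 with C13 and from 7.1e-10 to 0.393 averaged, and antigen presentation genes from 0.00251 to 0.214.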

Other observations

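The comparison of list shares below was chosen after the data were seen. Over all 12 libraries, the median nascent share of 9204 genes with a mean of at least 100 total reads was 2.69% (quartiles 1.81% and 4.02%), and 49 genes had more than 20%. Tnf stood at 63.2% ± 7.93, Nfkbia, an inhibitor of NF-kB, at 56.4% ± 6.89, Gdf15, a stress-induced cytokine, at 53.8% ± 8.54, and Ier3, an immediate-early gene, at 47.2% ± 9.9 (SD, n = 12). Zfp36, which promotes decay of mRNA with AU-rich elements, stood at 48.2% ± 15 and Ccl4 at 32.3% ± 9.19 (SD, n = 12). The mitochondrial transfer RNA mt-Ti stood at 67% ± 6.37 (SD, n = 12). Since all 12 libraries received 4-thiouridine, base changes from other sources cannot be told apart from labelling in these shares.

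Pooled over their members, immediate-early genes had a nascent share of 16.1% ± 4.42, interferon genes 6.93% ± 2.03, cytokine genes 5.78% ± 1.69, p53 targets 6.75% ± 1.24 and NF-kB genes 5.59% ± 1.47 (SD, n = 12). These 5 were among 9 lists above the library's own share in 12 of 12 libraries. By the median share of their genes, cytokine genes stood at 5.55% and interferon genes at 4.32%, the other order from the pooled shares. Lysosomal genes, with 1.81% ± 1.26, glycolysis genes, with 2.15% ± 1.26, and ribosomal protein genes, with 2.16% ± 1.10 (SD, n = 12), lay above it in 0 of 12. For each of these 8 lists, of 24 compared, the exact sign-flip p was 4.88e-04, the smallest that 12 libraries allow, and 9.77e-04 after adjustment. All 9 lists above the library's own share in 12 of 12 libraries had this p. It shows that a difference recurred across libraries of the same cell line. Genes were not treated as sampled, so the p does not set these gene classes apart from others.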
